A study of Dinoroseobacter shibae DFL 12 = DSM 16493 with 12 samples.

How the data were processed

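RNA of wild-type Dinoroseobacter shibae DFL 12 and of its luxI1 deletion mutant was measured on 12 Agilent 2-colour arrays, 2 biological replicates at each of 6 densities. Per the labels, cultures grew in the dark in minimal medium with succinate, RNA was labelled directly with Cy3 (wild type) and Cy5 (mutant), and the dyes were not swapped. Arrays of OD600 0.1 to 0.6 lay on slide 1 and were scanned in 1 session, and those of OD600 0.8 and stationary phase lay on slide 2 and were scanned in another.

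The scanner files hold 14999 spots per array from Agilent Feature Extraction 10.7.3.1. Per the file headers, their median spot and local background signals are raw intensity values. The deposited processed signals are intensity values that the software had corrected for background, spatial trend and dye. The deposited log ratio of the scanner files is a log10 ratio of red over green. The series table holds, as deposited by the authors, 1 log2 ratio per spot; limma is named for it without version or settings. Its values ran against the scanner log ratios (Pearson correlation across spots -0.907 to -0.950), so they are wild type over mutant and were used with the sign turned. Its columns have mean 0 over all spots and medians of -0.0566 to -0.114, so features at the array median count as slightly higher in the mutant there. It was used as an alternative.

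Of the spots, 14312 were gene spots and 687 controls, 137 of them negative controls. The files hold no mean spot signal, so median signals were corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, and log2 ratios of Cy5 over Cy3 were normalized within arrays by loess. Spots called non-uniform or population outliers by the scanner software were left out (78 to 203 per array), and 0 were saturated. For comparisons of densities within a strain, the mean log2 intensity of the channels was quantile normalized across arrays and each channel was derived from it and the ratio. Spots were averaged by probe (12476 probes). A probe was kept if at least a share of 0.5 of its spots was well above background in at least 1 channel on at least 2 arrays, which kept 10378 probes, and kept probes were averaged by feature. This left 3739 of 4102 features tested and 363 left out, with 4 missing values.

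Each comparison was fitted in limma with 1 coefficient per density and 1 variance over all densities. Contrasts were the mean over densities, each density, any difference among the densities, stationary phase against OD600 0.8, and OD600 0.6 against 0.1. The latter 2 were also fitted to the wild-type channel, and to the mutant channel after the data were seen. Two-sided moderated tests were adjusted by Benjamini-Hochberg over all features tested, and an adjusted p under 0.05 was a pass; at least 2-fold is a log2 of at least 1 in size. The contrasts, the settings and most alternatives were fixed before the data were examined. A density lies within 1 slide, so slide could not be fitted beside density. Correlations of replicate differences in the 15 pairs of densities ran from -0.00662 to 0.472, with 8 above 0.1. Arrays of the same replicate number may therefore share some variation. The planned fit left the replicate number out, and it entered as a block in an alternative. When 1 of the 2 arrays of a density was left out, the lone array was assumed to vary like the others.

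The planned rule for named genes took luxI1 with related regulators, the 10 highest and 10 lowest features of the mean comparison with 1 sign on all 12 arrays, the 5 highest and 5 lowest of the other comparisons, and up to 4 members of each gene list. Since the files do not pair identifiers with gene names, the 22 gene lists fixed beforehand could not be filled, and only 2 identifiers higher and 2 lower in the mean comparison are printed. The QSense features are printed because the probe name marks them as a group, and PhotoGC features are the members with the smallest p in the mean contrast and the wild-type stationary contrast. Both groups were chosen after the files were seen. They were tested with camera (preset correlation 0.01, and an estimated correlation), adjusted over 26 tests. A ratio in which 1 strain was not well above background on any array of a density is given as a lower bound. The dim strain was set, per array, at the higher of its own signal and the lowest level of a probe well above background on that array. Where its own signal was higher, as for RDRS03868 and PhotoGC37 in stationary phase, the bound equals the fitted ratio. The bounds hold for the normalization used and are open to dye bias.

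The fit was tested on simulated data with 200 changed features among 3739. With equal spread on all arrays, changes of log2 0.5, 1 and 2 in the mean comparison were recovered in 98.5%, 100% and 100% of features, with 7.44% of calls false. This share was 9.55% with the spread of each density kept, and 15.6% when changes were made to whole spot signals. For stationary phase against OD600 0.8 the shares were 62.7%, 94.0% and 100%, with 4.47% false. In the wild-type channel they were 0%, 13.4% and 60.6%, with 3.92% false. With the spread of each density kept, 39.6% of the calls for stationary phase against OD600 0.8 were false with 1 variance and 4.43% with a variance per density (array weights shared by the arrays of a density). The planned fit was kept, and counts with a variance per density are given as an alternative. The false shares depend on the number of changed features and do not carry over to counts in the data. When changes were made to spot signals, the estimated size depended on the background. A log2 change of 1 in the whole signal was estimated as 1.27 in the mean comparison and 1.88 for stationary phase against OD600 0.8. The same change in the signal above the negative controls was estimated as 0.72 and 0.58. For stationary phase against OD600 0.8, 39.4% and 27.3% of the calls were false in these 2 spot-level runs. Both had equal spread before processing and were fitted with 1 variance only.

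Alternatives were no background correction, normexp with offset 10, Agilent's processed signals, negative control spots as background, median centring, scale or quantile normalization, no filter, a strict filter (well above background in both channels on all 12 arrays), the brightest probe, the replicate block, fits within a slide or a density, a separate-channel fit, the series table, a variance per density, and leaving out arrays. Of these, the negative control background, the variance per density and leaving out both arrays of a density were chosen after the data were seen. Figures were drawn with matplotlib 3.10.9.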

Results

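The series compared a wild-type marine bacterium, Dinoroseobacter shibae DFL 12, with a mutant lacking luxI1, which encodes a synthase of acyl-homoserine lactone signals. Bacteria use such signals to sense their own density, and the labels describe the mutant as a quorum sensing null strain. Both strains were sampled at 6 densities, 5 of them in exponential growth from an OD600 (optical density) of 0.1 to 0.8 and the sixth in stationary phase, 6 h after the maximum. Each of 12 arrays carried wild-type RNA in the green Cy3 channel and mutant RNA in the red Cy5 channel, with 2 biological replicates per density. An array held 14312 gene spots for 4102 features, of which 3739 were tested. A feature is 1 identifier, mostly read by 3 probes. The number of arrays limits the precision. Median gene signal was 1.31 to 1.32 times the negative controls in the green channel of the stationary arrays and 1.53 to 1.59 times in their red channel, against 2.16 to 3.43 and 2.88 to 4.90 times on the other arrays. In stationary phase 26.5% and 28.0% of green spots were well above background, against 59.4% to 74.8% at the other densities. Log ratios of the 2 replicates of a density correlated across features at 0.861 (OD600 0.8) to 0.970, and features are not independent replicates.

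The deletion could not be checked by name. The files do not pair the array identifiers with gene names, and 0 features matched a locus tag of the reference table. Features are therefore described by group, by identifier or by the name of their first probe. Probes named QSense (12 features) and PhotoGC (57 features) formed 2 groups that were chosen after the files were seen, and the sources used here do not say what the names stand for. Each of these probes was printed on 10 spots, in all 360 QSense and 1680 PhotoGC spots of the 14312. Their features were thus averaged over more spots than most. This can favour them in counts of passing features and in set tests.

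The first comparison asked which transcripts differed between the strains across growth. A set of 203 features was lower in the mutant by at least 2-fold in the mean over the 6 densities, and 6 were higher by as much. Of the 203 features, 130 passed as at least 2-fold lower at all 6 densities and 172 at 5 or more. Their median log2 ratio of mutant over wild type was -2.12 at OD600 0.1, -2.12 at 0.2, -1.80 at 0.4, -1.54 at 0.6, -1.86 at 0.8 and -2.49 in stationary phase, and 0 of them passed as higher at any density. Wild-type signal was well above background on all 12 arrays in 149 of the 203, and mutant signal on none in 35.

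Among the lower features, RDRS03373 had a log2 ratio of -3.98 ± 0.09 (SE; SD of arrays 0.58, n = 12; adjusted p = 4.92e-11), lower on 12 of 12 arrays. RDRS02625 passed as lower too (n = 12 arrays; adjusted p = 1.12e-10), also on 12 of 12. Its mutant signal was well above background on 5 of 12 arrays and on none of OD600 0.6, 0.8 and stationary phase, where it was at least 5.31-fold, 10.2-fold and 22.6-fold lower. Its fitted mean of -3.96 therefore depends on the background. RDRS03868 was higher in the mutant by 4.80 ± 0.14 (SE; SD of arrays 1.65, n = 12; adjusted p = 3.53e-10) and RDRS00559 by 1.17 ± 0.04 (SE; SD of arrays 0.62, n = 12; adjusted p = 1.74e-09), each on 12 of 12 arrays. Wild-type signal was well above background on 10 arrays for RDRS03868 and on 3 for RDRS00559, so the size of the latter depends on the background. Among the 10 lowest and 10 highest features with 1 sign on all 12 arrays, the least extreme lay at -3.36 and 0.88.

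In all, 2837 of 3739 features passed, 1491 higher and 1346 lower, and 2628 of them differed by less than 2-fold. Every array had the mutant in Cy5, so the design cannot separate a difference in the mean, smaller or larger, from a constant dye effect. With the authors' deposited ratios, 68.9% of the passing features were higher in place of 52.6%, and with a strict filter on signal 36.9%. The count of at least 2-fold higher features depended on the background and the filter, from 1 without background correction to 22 with the scanner's processed signals.

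The QSense group held the lower feature with the smallest p among its members, QSense22, at -3.44 ± 0.04 (SE; SD of arrays 0.27, n = 12; adjusted p = 2.41e-13). It was lower on 12 of 12 arrays, between -3.17 and -3.87 at the 6 densities, with both channels well above background on 12 arrays. QSense25 passed as lower (n = 12 arrays; adjusted p = 2.48e-12), with mutant signal well above background on 0 of 12 arrays. It was at least 2.41-fold lower at OD600 0.1, 3.03-fold at 0.2, 2.34-fold at 0.4, 2.23-fold at 0.6 and 1.39-fold at 0.8. In stationary phase neither strain was well above background, so no bound is given there or for the mean. The members QSense10 (0.41), QSense13 (0.34), QSense19 (0.32), QSense34 (0.28), QSense16 (0.27) and QSense1 (0.23) passed as higher in the mean, and QSense1 did not pass within slide 2 alone (adjusted p = 0.227). In stationary phase QSense34 and QSense16 were well above background in neither strain, and QSense19 was not in the wild type. The size of these means therefore depends on the background. QSense4 (-0.05, adjusted p = 0.0888), QSense31 (0.02, adjusted p = 0.518) and QSense28 (0.02, adjusted p = 0.343) did not pass. These 3 were not stable, since QSense4 passed as lower in 6 of 28 alternatives (lowest adjusted p = 1.24e-07), QSense28 as higher in 3 of 27 (0.000179) and QSense31 as higher in 2 of 27 (0.000909). QSense4 also passed as lower in stationary phase (-0.29, adjusted p = 0.00165). The group as a whole gave no call in camera, a test of a set against the other features (adjusted p = 0.836, and adjusted p = 0.970 with an estimated correlation).

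The third QSense feature that passed as lower, QSense7, was split between its probes. Mutant signal of probes QSense7, QSense8 and general probes 2 and 3 was well above background on 0 arrays. In exponential phase it was at least 3.02-fold lower for QSense7, 4.35-fold for QSense8 and 4.61-fold for general probe 3, whose wild-type signal was well above background on 10 of 10 arrays. General probe 2 gave no bound. In stationary phase none of the 4 was well above background in either strain. Probe QSense9 was higher by 1.12 ± 0.32 (SD, n = 10) in exponential phase and general probe 1 by 1.19 ± 0.59 (SD, n = 10), the latter with wild-type signal well above background on 5 of 10 arrays. In stationary phase their wild-type signal was well above background on 0 of 2 arrays, and they were at least 3.88-fold and 3.65-fold higher. Among 3739 features, QSense7 was the 1 with a probe at least 2-fold higher and another at least 2-fold lower. Its mean log2 ratio of -0.86 became 1.74 with the brightest probe alone and describes neither set of probes.

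**Figure D1:**
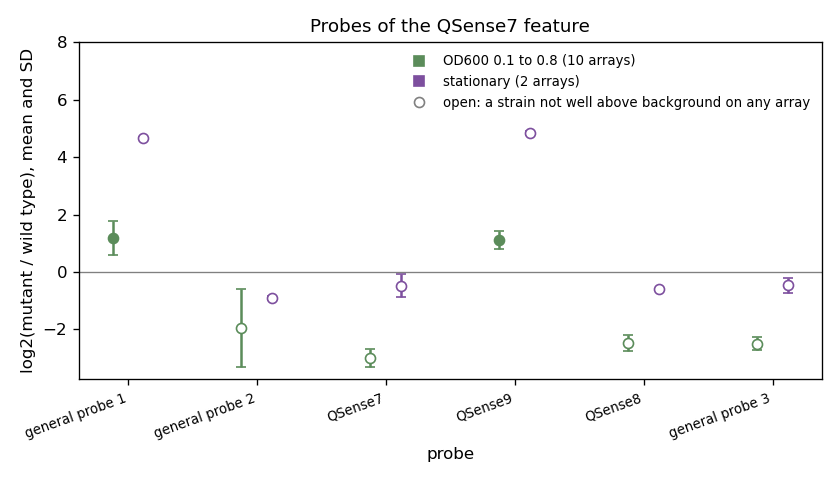
Log2 ratio of mutant over wild type of each probe of the QSense7 feature, as mean and SD over the 10 exponential arrays and over the 2 stationary arrays. Open symbols mark ratios in which a strain was not well above background on any array of the phase, so that their position depends on the background. Probe QSense9 and general probe 1 lie above 0 in both phases and the other 4 probes below 0.

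The comparisons at single densities asked when in growth the strains differed. The at least 2-fold differences went mostly down in the mutant at each density. There were 215 lower and 19 higher at OD600 0.1, 210 and 10 at 0.2, 196 and 11 at 0.4, 163 and 6 at 0.6, 197 and 42 at 0.8, and 345 and 45 in stationary phase. At both OD600 0.8 and stationary phase 165 features were at least 2-fold lower, where independent lists would share 18.2, and 7 were at least 2-fold higher, where they would share 0.505. The lists share probes, dyes and slide, so a constant probe or dye effect would also give an overlap above these numbers. RDRS03868 was higher by 5.69, 5.53, 5.87, 5.73 and 4.37 from OD600 0.1 to 0.8, and by 1.59 in stationary phase. Wild-type signal of RDRS03868 was well above background on 0 of 2 stationary arrays, so the ratio there is at least 3.01-fold with the normalization used. It did not pass with scale normalization, which gave a smaller ratio (0.99, adjusted p = 0.0958).

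**Figure D2:**
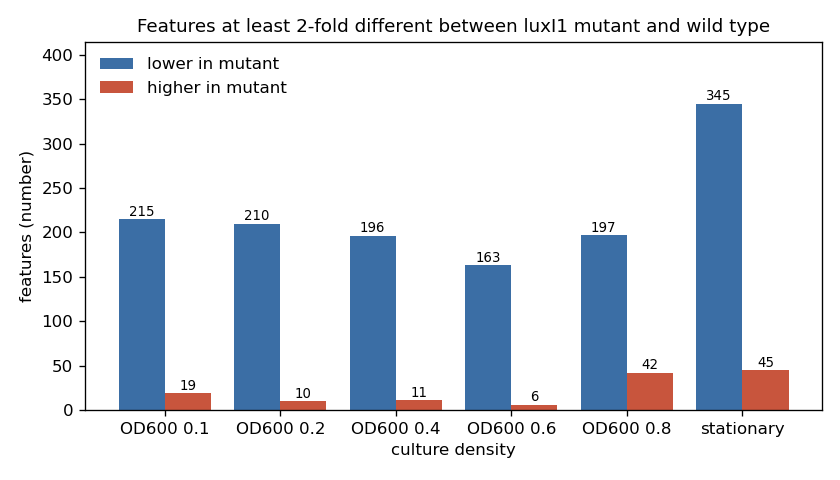
Number of features at least 2-fold higher or lower in the mutant that passed the test, at each of the 6 densities. The bars for lower features exceed those for higher features at each density, with 345 against 45 in stationary phase.

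Regardless of size, 1751 features passed at OD600 0.1, 1593 at 0.2, 1722 at 0.4, 1606 at 0.6, 2164 at 0.8 and 2493 in stationary phase. Replicate arrays differed most at OD600 0.8 (SD of the log2 ratio 0.248, against 0.0967 to 0.153 at the other densities). With a variance per density, chosen after the data were seen, 2272, 1801, 2246, 2245, 1068 and 2307 passed in this order, so OD600 0.8 went from the second highest count to the lowest. How the number of differences varied with density is therefore left open. The at least 2-fold counts changed less, to 195 lower and 39 higher at OD600 0.8. Without replicate 1 or replicate 2 of the density itself the counts fell to 1028 or 1042 at OD600 0.1, 987 or 1005 at 0.2, 890 or 1011 at 0.4, and 809 or 802 at 0.6.

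The next comparison asked whether the strain difference changed on entry into stationary phase, by setting the mutant-to-wild-type ratio in stationary phase against that at OD600 0.8. Both densities were on 1 slide, and a constant dye effect cancels here if both densities scale ratios alike. The simulated spot signals were not scaled alike. A log2 change of 1 in the whole signal was estimated as 1.88 here, against 1.27 in the mean comparison. Part of a constant ratio may therefore appear as a change. The PhotoGC group stood out, with a higher ratio in stationary phase in 50 of its 57 features and a lower one in 5. Of these features 33 rose by at least 2-fold, and the median difference was 1.23. The group passed camera with a preset correlation (adjusted p = 1.42e-35) but not otherwise (adjusted p = 0.105 with an estimated correlation). With a variance per density 47 PhotoGC features rose and 4 fell.

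PhotoGC160 changed by 2.79 ± 0.14 (SE; adjusted p = 8.62e-07) between the 2 densities, from -1.07 at OD600 0.8 to 1.72 in stationary phase. Its wild-type signal fell by 1.55 (adjusted p = 0.000500) and its mutant signal rose by 1.24 (adjusted p = 0.00328). PhotoGC37 passed with a fitted change of 2.30 (adjusted p = 8.62e-07). Its wild-type signal was well above background on 0 of 2 stationary arrays, so the ratio there is at least 2.75-fold with the normalization used and the size of the change is not determined. PhotoGC34 changed by 1.90 ± 0.14 (SE; adjusted p = 5.43e-06) and PhotoGC166 by 1.78 ± 0.09 (SE; adjusted p = 1.03e-06). The fitted change of PhotoGC134 was 0.42, and its outcome in limma was another in 6 of 26 alternatives (highest adjusted p = 0.283). Members were picked partly by the wild-type change over the same interval, so the sizes printed may lean large. PhotoGC155 was among the 5 PhotoGC features lower in the mutant in stationary phase, by at least 1.92-fold, since its mutant signal was well above background on 0 of 2 arrays there. In the mean it was at -2.35 ± 0.06 (SE; n = 12; adjusted p = 1.46e-10) and lower on 12 of 12 arrays. Its mutant signal was well above background on 7, so the size of this mean depends on the background. PhotoGC13, at 1.11, had a difference of -0.21 with its brightest probe alone, so its probes disagreed.

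Across all features 1708 passed this comparison, 452 with a higher and 1256 with a lower ratio in stationary phase. This count was too liberal. In simulated data in which each density kept its own replicate spread, 39.6% of the calls of this comparison were false, against 4.43% with a variance per density. False calls were also frequent in simulated spot signals. With equal spread put in before processing and changes made to whole spot signals, 39.4% were false with 1 variance. With changes made to the signal above the negative controls, 27.3% were. The spread after processing was not checked, so these runs cannot tell unequal spread from another source. A variance per density was not tried on these spot-level data, so its false share there is not known. With a variance per density 911 features passed in the data, 229 higher and 682 lower, and 910 of them were among the 1708. The at least 2-fold changes were 60 higher and 171 lower, or 60 and 165 with a variance per density. The fitted change of the RDRS03868 ratio was -2.78 (adjusted p = 0.00128), with -1.77 without replicate 1 of OD600 0.8 and -3.79 without replicate 2. The size of the fall is not determined, since wild-type signal was not well above background in stationary phase. RDRS00559 was well above background in neither strain on the stationary arrays, so its fitted values there are not read as a ratio or a change. The differences of RDRS03373 (-0.90, adjusted p = 0.0378) and RDRS02625 (-1.05, adjusted p = 0.0306) were lost with a variance per density (adjusted p = 0.280 and 0.273), and mutant signal of RDRS02625 was well above background at neither density. Both also changed sign with scale normalization (0.47 and 0.47) and were lost without any 1 array of OD600 0.8 or stationary phase, RDRS03373 also without 1 of OD600 0.6 (adjusted p = 0.0559 to 0.177 and 0.0771 to 0.126).

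The same question within exponential phase set the ratio at OD600 0.6 against that at 0.1, again on 1 slide. The PhotoGC ratio fell over this interval in 32 of 57 features and rose in 0, with a median difference of -0.46. Camera gave adjusted p = 2.69e-47 with a preset correlation and adjusted p = 0.103 with an estimated correlation. Without replicate 2 of OD600 0.1 the median was -0.42, but 0 features passed, PhotoGC features included. At single densities the PhotoGC group had 13 features higher and 18 lower at OD600 0.1, 26 and 6 at 0.2, 5 and 34 at 0.4, 5 and 40 at 0.6, 4 and 38 at 0.8, and 47 and 5 in stationary phase. Its median log2 ratios were 0.00, 0.09, -0.28, -0.47, -0.38 and 0.79 in this order. In stationary phase 23 of the 47 were at least 2-fold higher (camera adjusted p = 4.09e-16, and adjusted p = 0.276 with an estimated correlation). None of the 26 camera tests of the PhotoGC and QSense groups passed with an estimated correlation.

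**Figure D3:**
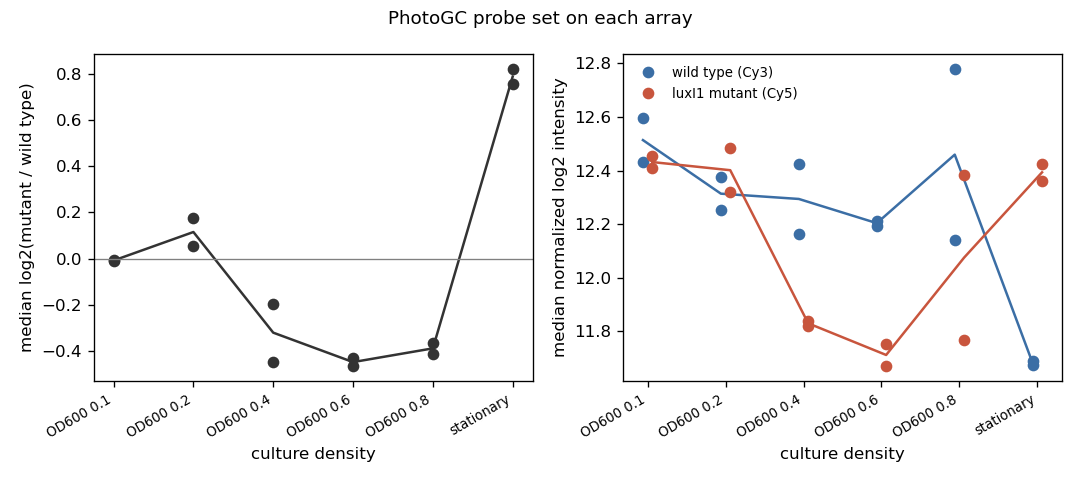
Median over the 57 PhotoGC features of the log2 ratio of mutant over wild type (left) and of the normalized log2 intensity of each strain (right) against density, 1 point per array, with lines through the mean of the 2 arrays of a density. The ratio lies at -0.41 and -0.37 on the OD600 0.8 arrays and at 0.82 and 0.76 on the stationary arrays.

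Across all features 143 passed from OD600 0.1 to 0.6, 96 higher and 47 lower, of which 7 rose and 0 fell by at least 2-fold. The share higher of 67.1% became 49.1% with Agilent's processed signals. The PhotoGC features, averaged over more spots than most, made up 32 of the 47. The count rested on single arrays, with 21 and 0 without replicate 1 and 2 of OD600 0.1, 30 and 11 without those of 0.6, and 263 and 261 without those of 0.8; 503 features had an unadjusted p under 0.05 in limma. With a variance per density 400 passed. Any difference among the 6 densities was called for 1937 features. These included 55 of 57 PhotoGC features, 7 of 12 QSense features and 187 of the 203 lower features. This test spans 2 slides and scan sessions, so it mixes slide with density. Within slide 1 273 features passed and within slide 2 795, each on fewer arrays and densities.

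The wild-type channel asked how the transcriptome changed with growth in the unmodified strain. From OD600 0.8 to stationary phase 31 PhotoGC features fell and 1 rose, with a median change of -0.77 (camera adjusted p = 1.54e-08, and adjusted p = 0.276 with an estimated correlation). PhotoGC34 fell by 1.64 ± 0.22 (SE; adjusted p = 0.000686) and QSense13 rose by 1.28 ± 0.25 (SE; adjusted p = 0.00449). RDRS02625 rose by 2.30 ± 0.50 (SE; adjusted p = 0.00678), with 1.90 (adjusted p = 0.0506) without replicate 1 of OD600 0.8, while RDRS03373 was at 1.43 (adjusted p = 0.0586). In all 1440 features passed, 808 higher and 632 lower, of which 660 rose and 504 fell by at least 2-fold. With a strict filter 84.4% of the passing features were higher in place of 56.1%. With a variance per density 1168 passed, 631 higher and 537 lower. Without replicate 1 or 2 of stationary phase 696 or 635 passed.

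From OD600 0.1 to 0.6 in the wild type, 0 PhotoGC and 0 QSense features passed in limma, and the PhotoGC median was -0.17 (camera adjusted p = 0.00266, and adjusted p = 0.540 with an estimated correlation). This median turned to 0.027 with the brightest probe, and with Agilent's processed signals it was -0.13 and no longer passed camera, so its direction stays open. In all 68 features passed, 25 higher and 43 lower, and 543 had an unadjusted p under 0.05. The direction of the split was not stable, since the 36.8% higher became 76.9% with Agilent's processed signals, 60.0% with the brightest probe and 77.8% with a strict filter. The 68 became 62 with a variance per density, 23 or 39 without replicate 1 or 2 of OD600 0.1, 43 without replicate 1 of 0.6, 127 or 132 without replicate 1 or 2 of 0.8, and 29 without either stationary array. At the 5 exponential densities wild-type signals varied more between replicates (SD 0.440 to 0.570) than ratios did, while in stationary phase they varied less (0.0816 against 0.153). Most green spots of the stationary arrays were not well above background.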

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

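For the results below, the low-signal tests, the test of single probes and the variance per density were chosen only after the result was seen, and the negative control background after the data were seen. Both low-signal tests replaced earlier versions restricted to probes well above background in both channels on the 4 arrays of slide 2. Those versions leaned towards features bright in the dimmer green channel (median stationary log2 ratio -0.54) and had given a PhotoGC median difference of 1.15 and counts of 415 against 88.

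Most of the 2837 features that passed the mean comparison of the strains, 2628 of them, differed by less than 2-fold. Of 100 regroupings that turned the sign of arrays, 1, the real one, gave as many. The highest other gave 2333, which points to a structure shared by the arrays. Turned signs set replicates of a density against each other and cancel any constant effect. The real signs were therefore favoured whatever shared effect the arrays carry, a dye effect included. The regroupings argue only against array signs at random and do not decide between causes. A dye effect that differs between probes would leave 2 different probes of a feature unrelated, and their mean ratios gave r = 0.800 across 2414 features. These features had passed on the mean of the same probes, a choice that by itself raises r. How much it did so was not tested, so the value argues against such an effect only in part. A dye effect that is the same at every density cannot be told apart from a constant strain difference (slide 1 against stationary phase, r = 0.443 across 2628 features), because the dyes were never swapped. The strain stays an open explanation for the small differences.

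The PhotoGC ratio differed between stationary phase and OD600 0.8 by a test of the difference itself, with a median of 1.23. The 47 PhotoGC features above the median of mean intensity gave 1.43. They were not chosen by signal on the stationary arrays, so they do not decide on low signal there. The 31 PhotoGC features with probes well above background in both channels on the 4 arrays of slide 2 gave 1.15. That choice leaned towards lower stationary ratios, so the rise was not limited to features at background. For the other features low signal stays open. A single deviating probe is argued against, since in 86.0% of 57 features every general probe was higher. With only replicate 1 of OD600 0.8 the median was 1.32, which argues against replicate 2 as the source. The size stays open, from 0.82 without background correction to 1.80 with the scanner's processed signals, and so does whether the features moved independently, since the call was lost with an estimated correlation. A response of the group to growth phase that differs between the strains may explain it and stays a hypothesis.

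More features differed by at least 2-fold in stationary phase (390) than at OD600 0.8 (239). Among the features above the median of mean intensity over all arrays the ratio of the counts was 1.97 (201 against 102). These features were not chosen by signal on the stationary arrays, and the earlier version leaned towards the green channel. Neither version can decide on low signal on the stationary arrays, which stays open. The local background correction is argued against, with 1.80 from the negative controls (500 against 278). The counts were 205 against 133 without background correction, 667 against 262 with the brightest probe and 286 against 73 with the strict filter, while with scale normalization the excess ended, at 193 against 197, because that setting makes the spread of ratios equal on all arrays. A wider spread of ratios on the stationary arrays, from the strains or from the hybridization, therefore stays open. A larger strain difference in stationary phase may explain it, which these data did not separate from that spread.

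The ratio of mutant over wild type also differed between densities in these results, each by a test of the difference itself. Any difference among the 6 densities was called for 1937 features. These densities span 2 slides and scan sessions, and within slide 1 and slide 2, on fewer arrays, 273 and 795 passed. A difference between stationary phase and OD600 0.8 was called for 1708 (911 with a variance per density), and one between OD600 0.6 and 0.1 for 143. The PhotoGC median changed by -0.46 from OD600 0.1 to 0.6, a call lost with an estimated correlation (adjusted p = 0.103), and 0 features passed without replicate 2 of OD600 0.1. From OD600 0.8 to stationary phase the fitted change was -2.78 for RDRS03868, whose size is not determined, since wild type was not well above background on the stationary arrays. It was -0.68 for RDRS00559, which cannot be read as a change of the ratio, since neither strain was well above background in stationary phase. It was 2.73 for the QSense7 feature, whose probes disagree and whose wild-type signal was at background in stationary phase. QSense10 changed by 0.44, which did not pass without background correction (adjusted p = 0.104), with scale normalization (0.216) or within slide 2 (0.0823). RDRS03373 (-0.90), RDRS02625 (-1.05), QSense1 (-0.41) and QSense28 (-0.30) no longer passed with a variance per density (adjusted p = 0.280, 0.273, 0.0989 and 0.0754), and RDRS02625 in the mutant and QSense28 in the wild type were well above background on 0 of 2 stationary arrays; the highest adjusted p over their alternatives were 0.604, 0.524, 0.0989 and 0.113 and the lowest 0.00326, 0.000392, 0.000336 and 0.00105.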

How the results depend on the processing

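The negative control background, the variance per density and the omission of both arrays of a density were chosen after the data were seen, as were the counts of at least 2-fold features. Of 374 alternative counts, 313 lay within 1.5 times the reported one and 61 outside. Of 3152 alternative values of named features and PhotoGC medians, 2932 were counted as unchanged and 220 were not. A passing value counted as unchanged if it kept direction and still passed. A value that did not pass as reported also counted as unchanged when its sign turned, so the 2932 include turned signs. With the replicate number as a block, 2888 features passed the mean comparison in place of 2837, and none of the other counts moved by more than 1.5 times. Signal of 1.31 to 1.59 times the negative controls limits the stationary ratios. Slide as a block could not be fitted beside density, and set tests of the 22 gene lists were not run. The cause was not tested except where named.

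Without background correction 1 feature was at least 2-fold higher and 268 passed for the ratio at OD600 0.6 against 0.1 (here the early contrast). With Agilent's processed signals these were 22 and 57, and 26 passed the early contrast in wild type. Median centring gave 13 features at least 2-fold higher. Negative control spots as background gave 12, and 85 for the early contrast, and the series table gave 76 for it. Scale normalization gave 958 for the ratio in stationary phase against OD600 0.8 (here the late contrast), and turned RDRS03373 and RDRS02625 in it to 0.47 and 0.47. A variance per density gave 2272, 1801, 2246, 2245, 1068 and 2307 at the densities in order, 911 for the late and 400 for the early contrast.

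The strict filter tested 1128 features, and so fewer passed: 976 in the mean, 42 and 1 at least 2-fold lower and higher, 666, 618, 678, 645, 790 and 897 at the densities in order, 806 and 73 for the late and early contrast, 675 and 36 for these in wild type, and 882 for any difference. PhotoGC13 turned to -0.74 in stationary phase and -0.23 in the late contrast. With the brightest probe QSense7 turned to 1.74 in the mean, PhotoGC13 to -0.71 and -0.21, and the PhotoGC median of the early contrast in wild type to 0.027, and 77 passed the early contrast; here a feature rests on 1 probe.

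Fits on fewer arrays gave fewer calls in most cases. Within slide 1, 285 passed the early contrast, 43 in wild type, and 273 for any difference. Within slide 2, 18 were at least 2-fold higher, 1322 passed at OD600 0.8, 795 for the late contrast and 795 for any difference, and the means of PhotoGC160 and PhotoGC37 turned to 0.33 and 0.31. With only the 2 arrays of OD600 0.8, 819 passed there, and without both of them 260 passed the early contrast.

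Leaving out 1 array at a time gave 1028 to 2019 at OD600 0.1, 987 to 1882 at 0.2, 890 to 1985 at 0.4 and 802 to 1912 at 0.6. The early contrast gave 0 (without replicate 2 of OD600 0.1) to 263, and 23 to 132 in wild type. The late contrast in wild type gave 635 (without replicate 2 of stationary phase) to 1658, and any difference 1270 (without the same array) to 2457.

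With the deposited ratios of the series table, 68.9% of the passing features were higher in the mean comparison (52.6% as reported), 70.4% at OD600 0.1 (876 of 1751 as reported), 65.5% at 0.2 (43.6%), 74.1% at 0.4 (54.5%), 77.8% at 0.6 (58.1%), 69.3% at 0.8 (56.6%) and 53.6% in stationary phase (40.3%). With the strict filter the shares were 36.9% in the mean, 39.8% at OD600 0.1, 27.7% at 0.2, 45.7% at 0.8, 25.4% in stationary phase, 14.9% for the late contrast (26.5% as reported) and 50.7% for the early one (67.1%). The brightest probe gave 33.1% at OD600 0.2, and negative control spots gave 55.3% for the early contrast.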

Other observations

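The tests of wild-type growth-phase changes and of neighbouring identifiers below, and the fits of the mutant channel, were chosen only after the result was seen; the test of the QSense7 probes was not.

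In the mutant channel, 20 PhotoGC features rose and 3 fell from OD600 0.8 to stationary phase, with a median change of 0.42 (camera adjusted p = 0.000327, and adjusted p = 0.558 with an estimated correlation). The median was 0.17 without replicate 1 of OD600 0.8 and 0.73 without replicate 2. QSense13 rose by 1.66 ± 0.23 (SE; adjusted p = 0.000703). RDRS03868 fell by 2.78 ± 0.68 (SE; adjusted p = 0.0111), which did not pass without replicate 1 of OD600 0.8 (-1.76, adjusted p = 0.0691), replicate 1 of stationary phase (-2.83, adjusted p = 0.0528) or replicate 2 of stationary phase (-2.72, adjusted p = 0.0641). In all 1574 features passed in the mutant, 746 higher and 828 lower (1206 with a variance per density), and the count ran from 853 (without replicate 2 of stationary phase) to 1775 when single arrays were left out, with both stationary arrays moving it by more than 1.5 times. The share higher of 47.4% became 71.2% with the strict filter. From OD600 0.1 to 0.6, 50 passed, 16 higher and 34 lower, including 5 PhotoGC features that fell. This count ran from 13 to 109 when single arrays were left out, and 10 of the 12 arrays moved it by more than 1.5 times. These were replicates 1 and 2 of OD600 0.1 (13 and 19), 0.2 (24 and 24), 0.6 (26 and 29), 0.8 (109 and 108) and stationary phase (13 and 13). Its direction was not stable, with the 16 of 50 higher becoming 81.8% with Agilent's processed signals, 65.1% with the brightest probe and 69.4% with the strict filter.

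In 16 features the wild-type signal was well above background on all 12 arrays and the mutant signal on none, and in 0 features the reverse held. The 2 replicate arrays of stationary phase were closer to each other in the wild-type channel (SD 0.0816) than those of any other density (0.440 to 0.570). On them 26.5% and 28.0% of green spots were well above background, so the closeness cannot be read as closer agreement of the cultures.

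The features lower in the mutant in exponential phase may be ones that rise in the wild type in stationary phase. The 190 features at least 2-fold lower on slide 1 had a median wild-type change of 1.35 from OD600 0.8 to stationary phase, measured on slide 2. Among 10000 random lists matched in intensity, the central 95% ended at 0.270 and the highest was 0.468. Of the 190 features, 115 passed as higher and 15 as lower in the wild type. Their median change in the mutant was 0.75.

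Neighbouring identifiers may change together. The mean log2 ratios of consecutive identifiers correlated at r = 0.478 across 3504 pairs of features, against 0.0507 as the highest of 1000 shuffles. Of the 203 features at least 2-fold lower, 79 lay in 11 runs of 3 or more consecutive identifiers, the longest of 15. Whether the order of identifiers follows the genome was not tested.

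Part of the QSense7 feature may be missing from the mutant. Its 4 lower probes were well above background in the mutant channel on 0 of 12 arrays, while in the wild type 3 of them were on 10 arrays and general probe 2 on 4. The other probes had higher ratios on 12 of 12 arrays. The sources used here do not name the gene behind the feature, so this could not be tied to the deletion.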
